A study of Homo sapiens with 21 samples.

How the data were processed

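Polyadenylated RNA of human vocal fold fibroblasts (VF) and dermal fibroblasts (DF) was sequenced after 48 hours in 3 media, with or without TGFb1. The deposited table held raw read counts of 58735 genes in 21 columns, 1 per sample. Per the submitters' processing notes, bcl2fastq 2.18.0.12 and STAR 2.5.3a were used with genome build hg38, without roles being given. The read counter, its strand setting and the annotation release are not given in the sources used here. All 100% of the gene IDs matched GENCODE release 29 (58780 genes), from which symbols, positions, GC content and exonic lengths were taken. Since the strand setting is not given, reads of a gene and of a partner on the opposite strand cannot be separated. The labels name a library kit for DNA, although the material was RNA. All 21 columns were used, and 0 entries lacked a gene name. Depth ran from 8495784 to 38529194 reads per column.

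Samples were assigned to 12 groups by cell type, medium and TGFb1 from the labels. In 3 pairs of samples of 1 group the titles carried the same well code with another prefix, and these were taken as repeat runs of 1 sample, which the labels do not state. Each pair was compared by a chi-square test of counts over genes with at least 20 reads and then summed, which left 18 libraries of 10246063 to 38529194 reads, 10 of VF and 8 of DF. The comparisons, gene lists, markers, rule for named genes and all alternatives but the last 2 named below were fixed before the data were examined.

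Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr with the groups of the fit, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05 over all genes tested. All tests were 2-sided. The TGFb1 effect in VF in DMEM and the 3 pairwise comparisons of media under TGFb1 used the 8 VF libraries of the 4 groups with 2 libraries each, with 1 coefficient per group. The TGFb1 effect over the 3 media was fitted within VF and within DF with medium as an additive term. The difference between these effects was tested in 1 fit of all 18 libraries, with a medium term and a TGFb1 term for each cell type. The difference of the TGFb1 effect between ECM and collagen in VF used the 10 VF libraries in 6 groups. There the untreated arms, with 1 library each, were assumed to vary like the other groups. ECM was compared with collagen in DF with TGFb1 as an additive term, and VF with DF as the mean over the 6 conditions. Errors of log2 fold changes are standard errors from the fit, and errors of expression levels are standard deviations of CPM, read counts relative to the library total, after TMM scaling. Residual degrees of freedom were 4 to 10. The common biological coefficient of variation was 6.1% in VF fitted by group. In additive fits, which count TGFb1 effects that differ by medium as spread, it was 16.2% in VF and 16.9% in DF.

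Of genes past the threshold, with an average log2 CPM of at least 2 and, between 2 groups, every library of one group above every library of the other, the 10 highest and the 10 lowest fold changes could be named. The text could also name up to 4 members of each list with the smallest adjusted p, and a panel of 20 genes in every comparison (ACTA2, TAGLN, CNN1, COL1A1, COL1A2, COL3A1, FN1, ELN, CTGF, TGFBI, TGFB1, SMAD7, HAS2, MMP1, MMP3, IL6, LOX, POSTN, DCN and 1 gene not reported here). HLA and immunoglobulin genes, genes missing from some genomes, genes of the sex chromosomes that differ between donors, pseudogenes and unnamed loci were left out of naming, since samples may come from single donors. Near copies such as CNTNAP3 and CNTNAP3B can share reads.

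The 21 gene lists were TGF-beta feedback and target genes; TGF-beta ligands, receptors and SMADs; BMP-responsive ID genes; contractile genes; collagens; matrix glycoproteins and proteoglycans; collagen processing; proteases and inhibitors; and hyaluronan genes. They further covered inflammatory, interferon-response and proliferation genes, cholesterol synthesis, hypoxia and glycolysis, amino acid and ER stress, oxidative stress and metallothioneins, YAP/TAZ targets, p53 targets, integrins, HOX genes and regional transcription factors. Lists were tested with camera of limma 3.58.1 on voom weights with a preset correlation of 0.01, adjusted over the 21 lists of a comparison, and again with an estimated correlation and with fry. camera compares a list with all other genes. The marker sets were those of fibroblasts (12 genes), epithelial cells (14), endothelial cells (10), skeletal muscle (12), immune cells (10), melanocytes (7), chondrocytes (9), adipocytes (8), pericytes or smooth muscle (10) and Schwann cells or nerve (8).

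Where all libraries of a group had 0 reads, a fold is given as a lower bound against a floor of 3 counts over the group. With 1 to 3 reads, a ratio is given with an exact counting interval at a confidence level of 0.95. Such floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The steps were tested on simulated data drawn from the real means and library sizes, with the common biological coefficient of variation of each comparison's own fit and 200 genes changed. Of 100 genes changed 2-fold and 100 changed 4-fold, the test recovered 96 and 100 for the TGFb1 effect in VF in DMEM, 87 and 99 for ECM against collagen in VF, and 71 and 90 for the difference of the TGFb1 effect between ECM and collagen, each at a spread of 6.1%. At 16.9% it recovered 88 and 100 for the TGFb1 effect in DF and 73 and 99 for ECM against collagen in DF, and at 16.5% 66 and 100 for VF minus DF. Those runs also made 9, 5, 10, 10, 9 and 10 false calls, and a second set at 8% in every comparison was run too.

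The alternatives were DESeq2 1.42.0 with its size factors, RLE size factors in edgeR, no filter on low counts, each library left out in turn, a replicate block, all 18 libraries in the fit, first runs only and runs as separate samples. A fit without 2 libraries that held genes of both cell types was added after the data had been seen. Each was the only untreated library of its cell type and medium, so that fit also leaves a medium or condition out of a comparison. VF minus DF was therefore also tested in DMEM alone, with 1 coefficient per group over the other 16 libraries (6 residual degrees of freedom), again added after the data had been seen. Tables were summarised with Python 3.11.15. DNA variants were not analysed here.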

Results

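Polyadenylated RNA was sequenced from human vocal fold fibroblasts (VF) and dermal fibroblasts (DF), collected 48 hours into culture. Cells were grown in DMEM with serum, in a hydrogel scaffold made from decellularised porcine extracellular matrix (ECM), or in collagen (COL). Each medium was used with and without TGFb1, the cytokine that drives fibroblasts towards a matrix-producing, contractile state. The stated purpose was to find out how the ECM hydrogel modulates this response in VF, with collagen and TGFb1 as the control for a typical fibrotic response. After 3 pairs of samples taken as repeat runs were summed, 18 libraries stood in 12 groups. VF had 2 libraries each in DMEM without TGFb1, DMEM with TGFb1, ECM with TGFb1 and collagen with TGFb1, and 1 each in untreated ECM and untreated collagen. DF had 2 libraries each in untreated ECM and ECM with TGFb1, and 1 in each other group. The members of such a pair carry the same well code with another prefix in their titles, which is all that the labels give on this, and they differed by little more than sampling noise, with a chi-square per degree of freedom of 1.04 to 1.06 over 3 pairs (p = 2.74e-06 to 0.000782 over 12704 to 13830 genes), against 5.88 to 28.5 over 7 pairs of separate samples. Each pair was counted as 1 sample. The titles give the replicates different well codes in all 6 groups with 2 libraries, and 5 libraries, each the only one of its group, carry a pair of joined codes. Whether wells were separate cultures, or donors differed, is not stated. Thus p-values measure only the spread of these samples around each fit, which may be technical.

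Library totals after summing ran from 10246063 to 38529194 reads, and 18769 to 22325 genes had at least 1 read. A floor of 3 counts corresponded to 0.078 to 0.293 CPM, the read count relative to the library total. All 12 fibroblast markers, among them COL1A1, DCN and VIM, had medians over 1 CPM in both cell types. None of 10 immune markers in VF and 1 in DF did so, and the highest immune value was 5.35 CPM, for CSF1R. Mitochondrial reads moved with the medium: in VF they took 0.35 to 0.70% of reads in DMEM, 0.70 to 1.75% in collagen and 1.65 to 2.75% in ECM. The 10 most abundant genes took 16.1 to 26.4% of reads in VF in DMEM and 7.09 to 10.5% in VF in ECM. Key genes lie, on genome build hg38, at chromosome 10, 88935074 to 88991339 (ACTA2), chromosome 17, 50183289 to 50201632 (COL1A1), chromosome 2, 215360440 to 215436172 (FN1), chromosome 5, 136028895 to 136063818 (TGFBI), chromosome 11, 102789920 to 102798160 (MMP1) and chromosome 8, 121612116 to 121641390 (HAS2). All are protein-coding, and counts were taken over whole genes. Gene models on the opposite strand overlap 30.1% of the exonic bases of ACTA2 and 82.4% of those of IGF1, so part of their counts cannot be assigned with certainty.

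**Figure D1:**
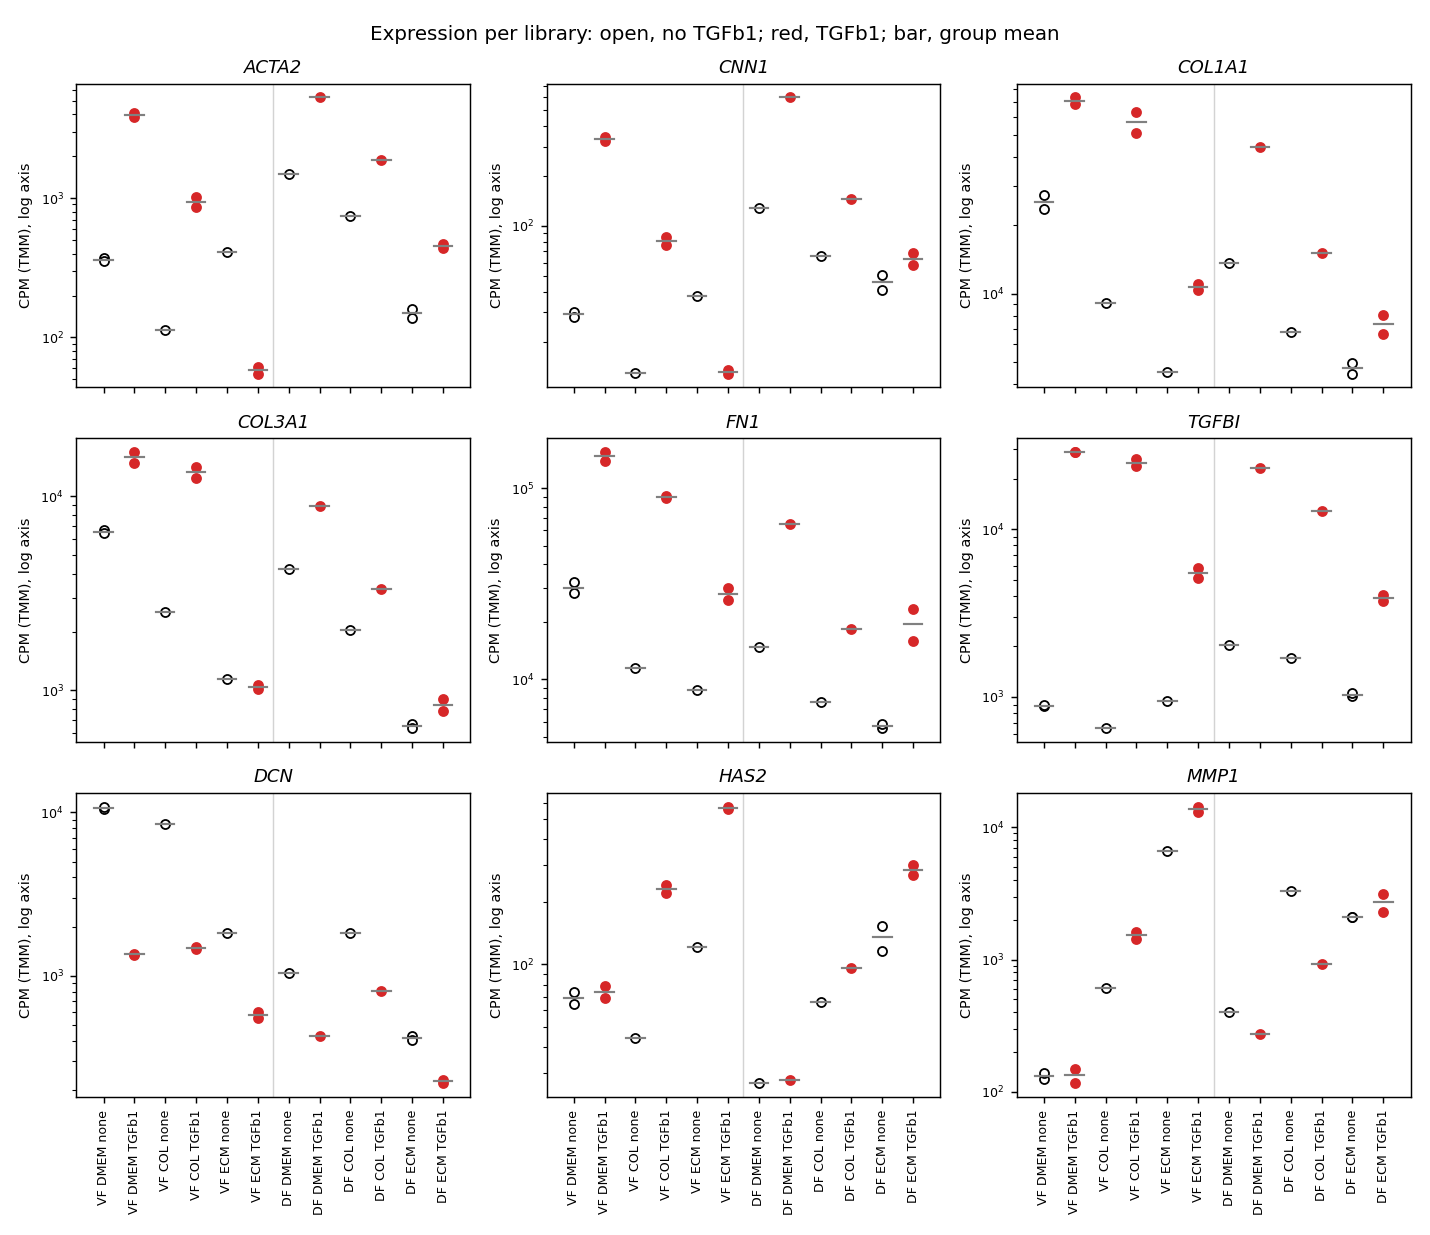
Normalised expression (CPM after TMM scaling, log axis) of 9 genes in each of the 18 libraries, by cell type, medium and TGFb1. Points are libraries, red where TGFb1 was added, and bars are group means. ACTA2 stood at 3950 CPM in VF in DMEM with TGFb1 and at 58.0 CPM in VF in ECM with TGFb1, while MMP1 stood at 132 and 13700 CPM in these groups.

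The response of VF to TGFb1 was first measured in DMEM, 2 libraries against 2. Smooth muscle actin (ACTA2), the marker of contractile myofibroblasts, rose from 361 ± 10.7 to 3950 ± 151 CPM (SD, n = 2 in each group), a log2 fold change of 3.44 ± 0.08 (SE). TGFBI, a secreted matrix protein named for its induction by TGF-beta, rose from 889 ± 15.5 to 28800 ± 31.8 CPM. Fibronectin (FN1) rose from 30200 ± 2720 to 147000 ± 10600 CPM and the type I collagen chain COL1A1 from 25500 ± 2610 to 70900 ± 3540 CPM. The small proteoglycans decorin (DCN) and lumican (LUM) fell by 2.97 ± 0.07 and 2.17 ± 0.07 on the log2 scale.

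Among the largest changes, the growth factor gene IGF1 had 0 reads without TGFb1 and 849 with it, at least 372-fold higher against a floor of 3 counts over the group. PLN, which encodes the calcium pump regulator phospholamban, went from 0 to 675 reads, at least 296-fold higher. Cardiac actin (ACTC1) rose by 6.92 ± 0.12. The ferritin receptor SCARA5 went from 1024 reads to 3, a ratio of 259 with a counting interval of 89 to 1260 at a confidence level of 0.95. The aldehyde dehydrogenase ALDH3A1 fell by 7.40 ± 0.29 and the glutamate receptor subunit GRIA1 by 7.24 ± 0.33.

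Of 22 TGF-beta feedback and target genes, 18 rose, 2 fell and 2 did not pass, and 20 passed when adjusted over the list alone. TGFBI (5.01 ± 0.09), the cytokine IL11 (4.02 ± 0.10) and the inhibitory SMAD7 (1.58 ± 0.08) were among those that rose (camera adjusted p = 5.01e-12, and adjusted p = 0.11 with an estimated correlation). The 22 ligands, receptors and SMADs moved both ways, 6 higher and 8 lower, with TGFB2 at 3.66 ± 0.10, the co-receptor TGFBR3 at -3.77 ± 0.11 and the signal transducer SMAD3 at -2.46 ± 0.08 (adjusted p = 0.293). Of 28 contractile genes 24 rose and 2 fell, including gut smooth muscle actin (ACTG2, 4.08 ± 0.09), calponin (CNN1, 3.52 ± 0.08) and transgelin (TAGLN, 2.52 ± 0.10), with 26 past when adjusted over the list alone (adjusted p = 1.14e-13, and adjusted p = 0.261 with an estimated correlation). Of 22 collagens 15 rose and 6 fell, with the basement membrane chain COL4A1 at 3.00 ± 0.09, COL10A1 at 5.25 ± 0.22 and COL3A1 at 1.27 ± 0.08 (adjusted p = 0.000249, and adjusted p = 0.322 with an estimated correlation). Of 22 collagen-processing genes 16 rose, among them the prolyl hydroxylase P4HA3 (3.65 ± 0.10), the lysyl hydroxylase PLOD2 (2.46 ± 0.07) and the crosslinking enzyme LOX (0.88 ± 0.08) (adjusted p = 0.000106, and adjusted p = 0.322 with an estimated correlation). The 35 matrix glycoproteins and proteoglycans divided, 19 higher and 12 lower, with periostin (POSTN) at 2.09 ± 0.07 and elastin (ELN) at 1.60 ± 0.10 beside the lower DCN and LUM (adjusted p = 0.104).

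Matrix-degrading proteases also moved both ways in DMEM, 8 of 28 higher and 13 lower. The membrane protease ADAM12 rose by 3.51 ± 0.08, the plasminogen activator PLAT fell by 2.66 ± 0.08 and stromelysin (MMP3) fell by 2.70 ± 0.16, while interstitial collagenase (MMP1) stood at 0.00 ± 0.10 (adjusted p = 0.977). The hyaluronan synthase HAS2 did not pass at 0.08 ± 0.08 (adjusted p = 0.401), and the hyaluronan-degrading CEMIP fell by 3.66 ± 0.10. Of 22 interferon-response genes 0 rose and 19 fell, including the RNA sensor IFIH1 (-1.71 ± 0.12) and the antiviral MX2 (-3.96 without the second DMEM library with TGFb1, and with all -3.12 ± 0.27) (adjusted p = 5.3e-09, and adjusted p = 0.282 with an estimated correlation). Inflammatory genes went both ways, 3 of 16 higher and 10 lower, with the prostaglandin synthase PTGS2 at 4.0 ± 0.12 and IL6 at 2.16 ± 0.13, against the NF-kB inhibitor TNFAIP3 at -2.78 ± 0.13 (adjusted p = 0.0546). Of 32 proliferation genes 27 rose and 0 fell, such as cyclin A2 (CCNA2, 1.40 ± 0.08) and the mitotic kinase AURKB (1.24 ± 0.12) (adjusted p = 4.08e-09, and adjusted p = 0.282 with an estimated correlation). Of 23 amino acid and ER stress genes 22 rose, such as the chaperone DNAJB9 (2.04 ± 0.08) and the pseudokinase TRIB3 (2.17 ± 0.09) (adjusted p = 3.41e-12, and adjusted p = 0.261 with an estimated correlation). In all, 8418 of 15046 genes passed in edgeR's quasi-likelihood test, 4142 higher and 4276 lower. With 2 libraries in a group and 4 residual degrees of freedom, these calls rest on a small spread between replicates (biological coefficient of variation 6.1%). Markers of other cell types moved too. Both of 2 adipocyte markers were lower (median -4.98), 2 of 3 melanocyte markers were lower and 1 higher (-0.95), the 1 immune marker was higher (2.71), 1 of 2 endothelial markers was higher (0.33) and 1 of 2 nerve markers lower (-1.64). Pericyte or smooth muscle markers (4 of 10 higher and 4 lower), epithelial (2 of 7 and 2), skeletal muscle (1 of 3 and 1) and chondrocyte markers (1 of 5 and 1) went both ways.

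The comparison closest to the stated purpose set ECM against collagen in VF, both with TGFb1, 2 libraries against 2. Myofibroblast and matrix genes were lower in ECM: ACTA2 was at 58.0 ± 4.21 CPM in ECM and 942 ± 105 CPM in collagen (SD, n = 2 each), a log2 difference of -3.99 ± 0.09. COL1A1 was at 10700 ± 456 against 57400 ± 8510 CPM, FN1 at 28000 ± 2770 against 89900 ± 1030 CPM, and TGFBI at 5500 ± 508 against 25000 ± 1680 CPM. MMP1 was higher in ECM, at 13700 ± 844 against 1540 ± 136 CPM, and so was HAS2, at 567 ± 9.92 against 231 ± 13.8 CPM.

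The largest differences towards ECM were those of the guanine nucleotide exchange factor PLEKHG4 (3.20 ± 0.13), MMP1 (3.18 ± 0.11) and the urokinase gene PLAU (2.99 ± 0.10). Towards collagen, IGF1 had 1 read in ECM against 2772 in collagen, a ratio of 1693 (interval 304 to 66912), and the peptidase inhibitor family member PI16 and ACTC1 were lower in ECM by log2 differences of -7.30 ± 0.28 and -6.49 ± 0.19. Of 28 contractile genes 26 were lower in ECM and 1 higher, and 27 passed when adjusted over the list alone. LMOD1, an actin filament nucleator of smooth muscle, was at -3.51 ± 0.12, CNN1 at -2.59 ± 0.09 and TAGLN at -1.87 ± 0.10 (adjusted p = 7.34e-18, and adjusted p = 0.0899 with an estimated correlation). Of 22 collagens 19 were lower and 2 higher, with COL3A1 at -3.66 ± 0.09, COL15A1 at -4.22 ± 0.10 and COL1A1 at -2.40 ± 0.09 (adjusted p = 7.47e-14, and adjusted p = 0.0899 with an estimated correlation). Of 35 matrix glycoproteins and proteoglycans 32 were lower, with 34 past when adjusted over the list alone. ELN was at -4.20 ± 0.11, the collagen-binding SPARC at -2.31 ± 0.08, DCN at -1.33 ± 0.07 and POSTN at -0.60 ± 0.07 (adjusted p = 2.15e-20, and adjusted p = 0.0883 with an estimated correlation). Of 22 collagen-processing genes 15 were lower and 4 higher, among the lower ones LOX (-1.98 ± 0.08) and the collagen chaperone SERPINH1 (-1.59 ± 0.08) (adjusted p = 3.58e-05, and adjusted p = 0.238 with an estimated correlation).

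TGF-beta feedback and target genes were lower in ECM in 14 of 22 cases and higher in 4, with CTGF at -1.28 ± 0.08 and the lipase inhibitor ANGPTL4 at 1.53 ± 0.08 (adjusted p = 0.000981, and adjusted p = 0.117 with an estimated correlation). Proteases were evenly divided, 12 of 28 higher and 12 lower: PLAT (1.42 ± 0.08) and cathepsin L (CTSL, 1.26 ± 0.07) were higher, and ADAM12 (-2.33 ± 0.07) and MMP3 (-1.02 ± 0.14) lower (adjusted p = 0.525). In this list and in the hyaluronan list the medians were -0.03 and -0.01 while camera's direction was up. Of 10 hyaluronan genes 4 were higher, HAS2 at 1.31 ± 0.08, and 2 lower, CEMIP at -4.27 ± 0.17 (adjusted p = 0.525). Of 16 inflammatory genes 0 were higher and 13 lower, among them the chemokine CXCL8 (-6.03 ± 0.26), the cytokines LIF (-2.48 ± 0.18) and IL6 (-0.68 ± 0.15) (adjusted p = 6.03e-06, and adjusted p = 0.0883 with an estimated correlation). Without the second ECM library IL6 stood at -0.42 and did not pass, and CXCL8, CEMIP and ACTC1 stood at -7.90, -4.88 and -7.27, the first ECM library having 1 read of CXCL8 and 3 of ACTC1. Of 22 interferon-response genes 14 were lower, and MX2 had 1 read in ECM against 55 in collagen (ratio 34, interval 6 to 1351), with adjusted p = 2.17e-05, and adjusted p = 0.255 with an estimated correlation. All 23 amino acid and ER stress genes were lower, such as the serine synthesis enzyme PSAT1 (-2.80 ± 0.08), the cystine transporter SLC7A11 (-3.32 ± 0.09) and TRIB3 (-3.41 ± 0.11) (adjusted p = 7.16e-24, and adjusted p = 0.0883 with an estimated correlation). Of 32 proliferation genes 30 were higher in ECM and 0 lower, BIRC5 and cyclin B1 (CCNB1) both at 1.56 ± 0.08 (adjusted p = 1.66e-22, and adjusted p = 0.0899 with an estimated correlation). YAP/TAZ targets were lower in 17 of 22 cases and higher in 4, with tissue factor (F3) at -3.81 ± 0.12, CYR61 at -1.57 ± 0.08 and the ectonucleotidase NT5E at 2.29 ± 0.08 (adjusted p = 0.000138, and adjusted p = 0.2 with an estimated correlation). In all, 6773 of 15046 genes passed, 3239 higher and 3534 lower in ECM. Mitochondrial reads were 1.85 to 2.75% in the ECM libraries and 0.70 to 0.85% in the collagen libraries, and thus moved with these gene groups. Of 10 pericyte or smooth muscle markers, a set that holds ACTA2, 5 were lower and 2 higher (median -0.28), of 7 epithelial markers 2 were lower and 2 higher (-1.43), and both of 2 endothelial markers were higher (1.54). The 1 immune marker was higher (1.25), 3 of 5 chondrocyte markers were lower (-0.48), and 1 of 3 skeletal muscle and 1 of 2 adipocyte markers were higher.

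**Figure D2:**
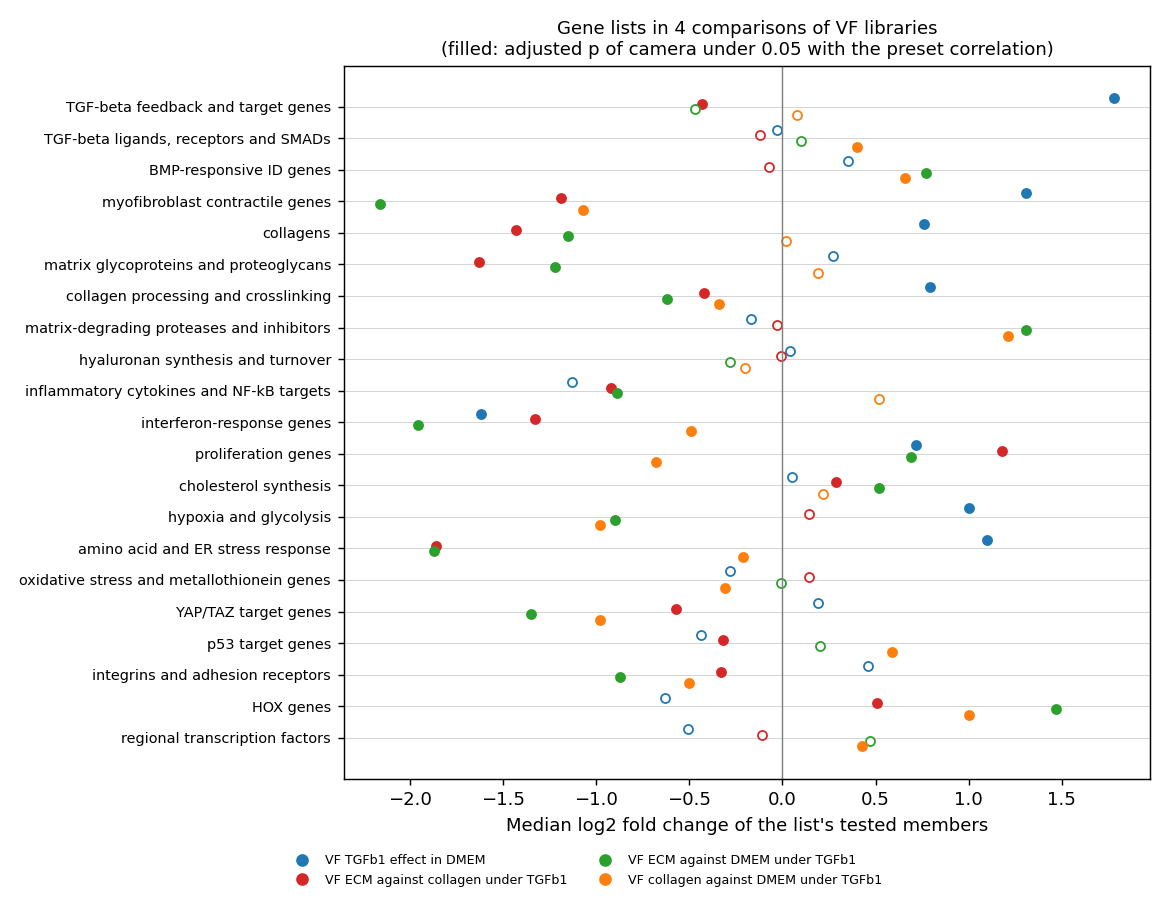
Median log2 fold change of the tested members of each of 21 gene lists (horizontal axis) in 4 comparisons of VF libraries. Filled points are lists past the threshold in camera with the preset correlation. For ECM against collagen under TGFb1 the medians were -1.19 for contractile genes, -1.43 for collagens, -1.63 for matrix glycoproteins and 1.18 for proliferation genes.

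Genes that TGFb1 changed in DMEM were then looked up in ECM against collagen, which shares no library with it. Of 4142 genes raised by TGFb1, 1438 were lower in ECM than in collagen, where independent lists would share 972.9, and 1022 were higher, where independent lists would share 891.7. Of 4276 genes lowered by TGFb1, 1004 were higher in ECM (920.5 for independent lists) and 989 lower (1004.3). Across the 8418 called genes the signs were opposite for 52.7%, and Spearman's rho across genes was -0.108. Genes are not independent replicates, so no test was made of these shares.

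With TGFb1 in both media, VF in ECM differed from VF in DMEM in 8718 of 15046 genes, 4435 higher and 4283 lower in ECM. ACTA2 was lower by a log2 difference of -6.07 ± 0.10, the actin-bundling SYNPO2 by -6.49 ± 0.11 and ACTG2 by -6.42 ± 0.13, and 27 of 28 contractile genes were lower (adjusted p = 6.58e-20, and adjusted p = 0.118 with an estimated correlation). MMP1 was higher by 6.70 ± 0.12, the membrane-type collagenase MMP14 by 3.05 ± 0.08 and the urokinase receptor PLAUR by 2.53 ± 0.08, and 22 of 28 proteases and inhibitors were higher, 4 lower (adjusted p = 2.8e-07, and adjusted p = 0.146 with an estimated correlation). The vesicle protein SYTL5 (7.23 ± 0.19), BTBD11 (7.25 ± 0.29) and RIPOR3 (7.02 ± 0.23, and 9.46 without the second DMEM library with TGFb1, the other having 1 read) were the genes furthest towards ECM, and ACTC1 (-10.26 ± 0.16, and -11.04 without the second ECM library) and PI16 (-8.40 ± 0.25) stood at the other end, together with IGF1, with 1 read in ECM and 849 in DMEM (ratio 713, interval 128 to 28201). Of 22 collagens 17 were lower, COL4A1 at -5.52 ± 0.10 and COL3A1 at -3.92 ± 0.09, and 5 higher, COL10A1 at 4.23 ± 0.09 (adjusted p = 2.53e-06, and adjusted p = 0.156 with an estimated correlation). HAS2 (2.96 ± 0.08), TGFB1 itself (1.49 ± 0.08), IL11 (1.68 ± 0.08) and ANGPTL4 (5.18 ± 0.10) were higher, while TGFBI (-2.37 ± 0.08) was lower. Hypoxia and glycolysis genes were lower in 18 of 22 cases, the glucose transporter SLC2A1 at -2.29 ± 0.08 and BNIP3 at -1.88 ± 0.08 (adjusted p = 2.8e-07, and adjusted p = 0.118 with an estimated correlation). YAP/TAZ targets were lower in 20 of 22 cases, CYR61 at -3.92 ± 0.08 and CRIM1 at -2.72 ± 0.07 (adjusted p = 1.37e-09, and adjusted p = 0.118 with an estimated correlation). Proliferation genes were higher in 25 of 32 cases, the replication helicase subunit MCM7 at 0.86 ± 0.08 and the kinase PLK1 at 1.04 ± 0.09 (adjusted p = 2.53e-06, and adjusted p = 0.237 with an estimated correlation). Markers of other cell types moved with these groups: of 10 pericyte or smooth muscle markers 8 were lower and 2 higher (median -1.24), of 7 epithelial markers 4 were lower and 2 higher (-2.64), and both of 2 endothelial markers were higher (3.09). The 1 immune marker (2.71) and 1 of 2 adipocyte markers were higher, 1 of 2 nerve and 1 of 3 skeletal muscle markers lower, and chondrocyte (2 of 5 higher and 2 lower) and melanocyte markers (1 of 3 and 1) went both ways. Mitochondrial reads were 1.85 to 2.75% in ECM and 0.46 to 0.70% in DMEM.

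Collagen against DMEM, both with TGFb1, gave 7276 genes in VF, 3559 higher and 3717 lower in collagen. Contractile genes were lower here too, 26 of 28 with 0 higher, with SYNPO2 at -3.54 ± 0.08, ACTG2 at -3.58 ± 0.09 and ACTA2 at -2.08 ± 0.08 (adjusted p = 5.82e-18, and adjusted p = 0.0978 with an estimated correlation). Collagens divided evenly, 9 of 22 higher and 9 lower: COL10A1 was at 4.15 ± 0.09, COL4A1 at -2.16 ± 0.09, COL1A1 at -0.31 ± 0.09 and COL3A1 at -0.26 ± 0.08 (adjusted p = 0.569), and DCN did not pass at 0.12 ± 0.07. Without the second collagen library COL1A1 and COL3A1 both stood at -0.17 and did not pass, without the first COL1A1 stood at -0.47, and COL3A1 did not pass without the first DMEM library with TGFb1 (-0.16). With all 18 libraries in the fit neither passed (adjusted p = 0.0547 and 0.0645). Proteases were higher in 22 of 28 cases, with MMP11 at 3.61 ± 0.16, MMP14 at 2.69 ± 0.07 and MMP1 at 3.52 ± 0.11 (adjusted p = 4.04e-10, and adjusted p = 0.0978 with an estimated correlation). Proliferation genes were lower in 27 of 32 cases, the kinase AURKA at -1.31 ± 0.09 and the topoisomerase TOP2A at -1.16 ± 0.09 (adjusted p = 7.36e-09, and adjusted p = 0.191 with an estimated correlation). Of 19 p53 targets 16 were higher, the cell cycle inhibitor CDKN1A at 0.85 ± 0.07 and FDXR at 1.62 ± 0.11 (adjusted p = 2.88e-07, and adjusted p = 0.0923 with an estimated correlation). Hypoxia and glycolysis genes were lower in 17 of 22 cases, SLC2A1 at -2.02 ± 0.08 and lactate dehydrogenase (LDHA) at -1.47 ± 0.07 (adjusted p = 4.04e-10, and adjusted p = 0.0923 with an estimated correlation). Inflammatory genes went both ways, 9 of 16 higher and 5 lower, with the chemokines CXCL6 at 4.26 ± 0.25 and CXCL8 at 2.29 ± 0.15 and PTGS2 at -1.76 ± 0.10 (adjusted p = 0.128). The largest differences were those of TMEM132B (6.19 ± 0.34, and 10.72 without the second DMEM library with TGFb1, a value that depends on the prior count as the other had 0 reads), the axon guidance gene DRAXIN (5.72 ± 0.32, and 6.83 and 4.78 without the first and the second DMEM library with TGFb1) and the transcription factor FOXQ1 (5.25 ± 0.31) towards collagen. Towards DMEM they were TM4SF20 (118 reads against 0, at least 54-fold), the stretch-induced ANKRD1 (-5.89 ± 0.18) and the neurotrophic factor receptor GFRA1 (-4.15 ± 0.09). Of 10 pericyte or smooth muscle markers 7 were lower in collagen and 2 higher (median -0.86), of 7 epithelial markers 3 were lower and 1 higher (-0.51), and 1 of 2 endothelial markers was higher (1.55). The 1 immune marker (1.46), 1 of 2 adipocyte markers and 2 of 3 melanocyte markers (0.95) were higher, the other melanocyte marker, 2 of 3 skeletal muscle (-1.19) and 1 of 2 nerve markers lower, and 2 of 5 chondrocyte markers were higher and 2 lower. Mitochondrial reads were 0.70 to 0.85% in collagen and 0.46 to 0.70% in DMEM.

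The comparisons that follow use 2 libraries that stood apart, those labelled VF untreated in ECM and DF untreated in collagen. Each was closest to the other (Spearman's rho 0.985 across genes), and both held genes that other libraries of only 1 cell type expressed. A set of 29 autosomal genes, at over 5 CPM in each of the other DF libraries and under 0.3 CPM in each of the other VF libraries, summed to 380 CPM in the library labelled VF and to at most 0.99 CPM in the other VF libraries. HOXA10, one of them, had 0 reads in the 9 other VF libraries and 14.9 CPM in this one (these sums and this value without TMM scaling). A set of 6 VF-only genes, defined the other way round, summed to 56.5 CPM in the library labelled DF and to at most 0.47 CPM in the other DF libraries. In the library labelled VF this set was at 115 CPM, as in VF with TGFb1 (83.7 to 129 CPM) and below the other untreated VF libraries (1126.5 to 1260.5 CPM). TGFBI, in contrast, stood there at 940 CPM after TMM scaling, beside group means of 650 and 889 CPM in other untreated VF and of 5500 to 28800 CPM in VF with TGFb1. The number of genes called is therefore also given without these 2 libraries wherever that fit could be made, and the count of a gene list described there where it moved by over 1.5 times, an alternative chosen after seeing the data. Each was the only untreated library of its cell type and medium. Without them the TGFb1 effect in VF rested on DMEM and collagen, that in DF on DMEM and ECM, collagen in DF on 1 library, and VF against DF on 4 of the 6 conditions. A value that moved therefore does not separate these libraries from the medium or condition that left with them, and the same holds for any other library that was alone in its group. The 4 comparisons above do not use them.

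**Figure D3:**
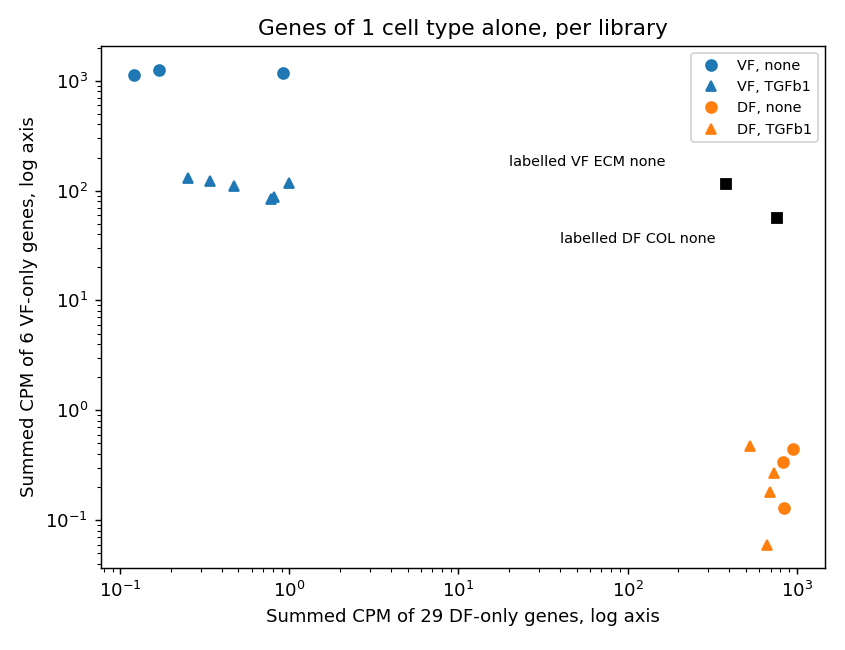
Summed expression (CPM, log axes) of 29 DF-only and 6 VF-only autosomal genes in each of the 18 libraries. The libraries labelled VF ECM none and DF COL none (squares) held both sets, at 380 and 115 CPM and at 763 and 56.5 CPM. The sets were chosen on the other 16 libraries, so the separation of those 16 follows from the choice.

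Over the 3 media together, TGFb1 raised its feedback and target genes in VF, 20 of 22 with 1 lower, and lowered interferon-response genes, 0 of 22 higher and 18 lower. The transcription repressor BHLHE40 rose by 4.06 ± 0.20, IL11 by 4.18 ± 0.24 and TGFBI by 4.30 ± 0.50 (6 libraries against 4; list adjusted p = 8.67e-10, and adjusted p = 0.373 with an estimated correlation). Over DMEM and collagen, without the 2 libraries, TGFBI rose by 5.11 ± 0.12. Of these 22, 18 rose in that fit, with adjusted p = 0.0478 with an estimated correlation. The antiviral MX1 fell by 3.22 ± 0.19 and IFIH1 by 1.84 ± 0.16 (adjusted p = 8.5e-09, and adjusted p = 0.373 with an estimated correlation). Proliferation genes rose in 31 of 32 cases, AURKB by 1.25 ± 0.09 and CCNA2 by 1.51 ± 0.12 (adjusted p = 1.2e-12, and adjusted p = 0.373 with an estimated correlation). FN1 (2.28 ± 0.24) and COL1A1 (1.71 ± 0.25) rose, and DCN (-2.49 ± 0.20), LUM (-1.97 ± 0.11) and the NF-kB inhibitors TNFAIP3 (-2.48 ± 0.11) and NFKBIA (-1.39 ± 0.10) fell. The ER chaperone HSPA5 rose by 1.38 ± 0.16. The alcohol dehydrogenase ADH1B had 0 reads with TGFb1 and 1433 without, at least 652-fold lower. ACTA2 did not pass at 1.52 ± 1.46 over the 3 media and rose by 3.28 ± 0.11 over DMEM and collagen. ECM, the medium left out there, had the lowest mean of ACTA2 under TGFb1 in VF, 58 CPM against 942 CPM in collagen. With no filter on low counts ACTA2 passed (1.52 ± 0.15) on the same reads, which adds no evidence. TAGLN was at 1.70 ± 0.78 over the 3 media and at 2.95 ± 0.25 over DMEM and collagen, and also passed without the first ECM library with TGFb1 (2.21) and in DESeq2 (adjusted p = 0.0262). Contractile genes were higher in 8 of 28 cases over the 3 media and in 23 over DMEM and collagen. HOX genes, which mark body position, were lower in 19 of 22 cases. All 176 HOXA10 and 194 HOXC11 reads were in the library labelled VF untreated in ECM. With the 2 libraries left out, 4 HOX genes could be tested, 3 lower. The test called 8508 of 16754 genes, 4022 higher and 4486 lower, and 9093 over DMEM and collagen, of which 7730 were shared. Markers of other cell types moved both ways, with 3 of 9 epithelial markers higher and 2 lower (median -1.05), 2 of 10 pericyte or smooth muscle markers higher and 4 lower (-0.35), and 3 of 4 adipocyte markers lower (-2.48).

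In DF, TGFb1 over the 3 media (4 libraries against 4) raised the TGF-beta inhibitor PMEPA1 by 3.24 ± 0.12, IL11 by 2.75 ± 0.18, TGFBI by 2.55 ± 0.26 and CTGF by 2.28 ± 0.18. Of 22 TGF-beta target genes 16 rose and 0 fell (adjusted p = 1.64e-19, and adjusted p = 0.217 with an estimated correlation). Of 28 contractile genes 16 rose, ACTA2 by 1.59 ± 0.13 and tropomyosin (TPM1) by 1.56 ± 0.13, with 20 past when adjusted over the list alone (adjusted p = 6.18e-13, and adjusted p = 0.396 with an estimated correlation). ELN (2.06 ± 0.13), FN1 (1.74 ± 0.19), COL5A1 (1.62 ± 0.15) and COL1A1 (1.03 ± 0.19) rose and DCN (-1.06 ± 0.12) fell. Inflammatory genes fell in 15 of 21 cases, the chemokines CXCL1 by 2.5 ± 0.16 and CXCL6 by 2.31 ± 0.23 (adjusted p = 3.22e-14, and adjusted p = 0.293 with an estimated correlation). Amino acid genes rose in 14 of 23 cases, PSAT1 by 1.38 ± 0.13 and the folate enzyme MTHFD2 by 1.05 ± 0.14 (adjusted p = 8.39e-15, and adjusted p = 0.308 with an estimated correlation). Of 32 proliferation genes 0 passed in edgeR, 0 at an unadjusted p under 0.05 and 0 in DESeq2, TYMS standing at -0.48 ± 0.22 (adjusted p = 0.00329 with no filter on low counts) and PCNA at -0.16 ± 0.16, and MMP1 did not pass at -0.39 ± 0.36. IGF1 (4.94 ± 0.29), the sialyltransferase ST6GAL2 (4.64 ± 0.15) and CHRNA9 (4.55 ± 0.24) rose furthest with all libraries, and CEMIP (-5.88 ± 0.21), GPM6B (-4.97 ± 0.93) and the pentraxin PTX3 (-4.92 ± 0.53, and -4.06 ± 0.26 over DMEM and ECM) fell furthest, the value of IGF1 depending on the prior count as untreated DF in ECM were at 0.0363 CPM. PTX3 stood at -5.70 and -5.60 without the treated and the untreated DMEM library. GPM6B stood at -2.66 without either collagen library and at -6.20 without the first ECM library with TGFb1, and did not pass without either DMEM library (-5.28 and -5.30) or with no filter on low counts (-4.98, adjusted p = 0.137). The test called 1934 of 15791 genes, 889 higher and 1045 lower. Over DMEM and ECM, without the 2 libraries, it called 1162, 1093 of them shared. Leaving out the library in collagen with TGFb1, the second in ECM with TGFb1 or the second untreated in ECM gave 1181, 1158 and 1249. Of 10 pericyte or smooth muscle markers, ACTA2 included, 4 were higher and 0 lower (median 0.15), and of 7 epithelial markers 2 were higher and 1 lower (-0.33).

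The difference between the responses of VF and DF to TGFb1 was tested directly. The ligand TGFB3 (difference 2.24 ± 0.25), BHLHE40 (1.71 ± 0.29), the hyaluronan-binding TNFAIP6 (1.93 ± 0.26) and the cell cycle genes AURKB (1.33 ± 0.26) and CCNA2 (1.40 ± 0.29) had higher effects in VF. LUM (-1.70 ± 0.17), DCN (-1.44 ± 0.25), the BMP pseudoreceptor BAMBI (-1.60 ± 0.20), the vasodilator peptide ADM (-2.21 ± 0.24), MX2 (-2.52 ± 0.66) and the redox gene TXNRD1 (-0.82 ± 0.13) had lower ones. All of these passed also without the 2 libraries. That fit sets VF in DMEM and collagen against DF in DMEM and ECM, so the difference was also taken in DMEM alone, chosen after seeing the data. There the DF effect is that of 1 library against 1, with no replicate check, and every p-value given for DMEM assumes that these vary like the other groups. On that assumption all 11 genes passed in DMEM too, with BHLHE40 at 0.95 ± 0.19, AURKB at 2.29 ± 0.25 and CCNA2 at 2.32 ± 0.18. MX2 did not pass when any 1 of 10 other libraries was left out (adjusted p = 0.0519 to 0.103). ACTA2 stood at -0.07 ± 1.44 (adjusted p = 0.991) and, without the 2 libraries, at 1.57 ± 0.17 (adjusted p = 1.85e-05). In DMEM alone it stood at 1.59 ± 0.18 (adjusted p = 4.85e-06), again with 1 DF library in each arm, so no direction is given for it over the media. COL1A1 (0.67 ± 0.33) and FN1 (0.54 ± 0.30) did not pass, but did without a filter on low counts (adjusted p = 0.000901 and 0.0133). That setting leaves their reads as they were, so it adds no evidence. In DMEM alone neither passed, COL1A1 lying on the other side of 0 at -0.27 ± 0.20 (adjusted p = 0.437) and FN1 at 0.10 ± 0.23 (adjusted p = 0.845). Contractile genes were higher in VF in 1 of 28 cases and lower in 2 (adjusted p = 0.831), and without the 2 libraries higher in 12 and lower in 2 (adjusted p = 5.7e-07, and adjusted p = 0.421 with an estimated correlation). In DMEM alone 8 were higher and 2 lower (adjusted p = 0.000179, and adjusted p = 0.378 with an estimated correlation). TGF-beta target genes were higher in 4 of 22 cases and lower in 1 (adjusted p = 0.00136, and adjusted p = 0.426 with an estimated correlation), and without the 2 libraries higher in 8 and lower in 3 (adjusted p = 0.000107, and adjusted p = 0.383 with an estimated correlation). In DMEM alone 8 were higher and 4 lower, and the list did not pass (adjusted p = 0.139). Collagens were higher in 1 of 23 cases and lower in 2 (adjusted p = 0.311), and without the 2 libraries higher in 4 and lower in 1 (adjusted p = 0.000283, and adjusted p = 0.438 with an estimated correlation). In DMEM alone 3 were higher and 6 lower, with a median of -0.27, and the list did not pass (adjusted p = 0.213). Proliferation genes differed in 7 of 32 cases, all higher in VF, with 27 past when adjusted over the list alone (adjusted p = 5.49e-14, and adjusted p = 0.426 with an estimated correlation), and in 16 without the 2 libraries. In DMEM alone 31 were higher (adjusted p = 2.8e-39, and adjusted p = 0.0123 with an estimated correlation). Interferon-response genes were lower in VF in 1 of 22 cases, and in 14 without the 2 libraries (adjusted p = 6.58e-09, and adjusted p = 0.383 with an estimated correlation). In DMEM alone 14 were lower too (adjusted p = 5.69e-10, and adjusted p = 0.223 with an estimated correlation). HOX genes were lower in 18 of 30 cases with all libraries, HOXC11 and HOXA10 leading with the channel gene ANO4. These 18 had at most 2 reads each summed over the other 9 VF libraries. With these libraries left out 1 of 29 was lower, HOXB3, not one of the 18 and named after its value was seen. MAGEC2, CNTNAP3 and the kinase gene BLK led the other end and did not pass without them or without the DF library in collagen with TGFb1, nor did BLK in DESeq2, CNTNAP3 being one that may share reads with its near copy CNTNAP3B. The test called 1373 of 17098 genes, 503 higher and 870 lower, and 2410 without the 2 libraries, 1119 of them shared. In DMEM alone it called 2476 of 16946, 833 of them shared with the fit of all libraries. Leaving out the library labelled VF untreated in ECM alone gave 2300, and no filter on low counts gave 2305.

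Whether TGFb1 acted differently on VF in ECM and in collagen could be set out only as a difference of differences with 1 untreated library in each medium, that in ECM being 1 of the 2 that stood apart. Its values and p-values therefore compare these libraries as labelled, with a spread taken from the other groups, and do not separate a difference in the TGFb1 effect from the makeup of that library. ACTA2, at 412 CPM in the untreated ECM library and 114 CPM in the untreated collagen library, had a difference of -5.83 ± 0.15, CNN1 of -4.12 ± 0.17, the basement membrane collagen COL15A1 of -4.62 ± 0.17, COL3A1 of -2.49 ± 0.14 and the matrix protein tenascin C (TNC) of -4.84 ± 0.14. Of 23 collagens 21 were lower (adjusted p = 2.18e-27, and adjusted p = 0.0569 with an estimated correlation), as were 22 of 28 contractile genes (adjusted p = 1.07e-30, and adjusted p = 0.0605 with an estimated correlation). All 23 amino acid genes were lower, MTHFD2 at -2.96 ± 0.14 and PSAT1 at -2.79 ± 0.14 (adjusted p = 1.66e-31, and adjusted p = 0.0569 with an estimated correlation). The chemokines CXCL8 (-7.42 ± 0.29) and CXCL1 (-5.18 ± 0.32), TGFBI (-2.68 ± 0.14), the collagen-binding integrin ITGA11 (-8.95 ± 0.29) and CYR61 (-3.52 ± 0.14) were lower. Without the second ECM library with TGFb1 CXCL8, CXCL1 and ITGA11 stood at -9.31, -4.48 and -9.70, and CXCL1 at -5.81 without the first. HAS2 (-0.13 ± 0.14) and MMP1 (-0.26 ± 0.16) did not pass. IGF1, PLN, TM4SF20 and CD36 passed too, but at least 1 of the 4 arms had no more than 3 reads in each, so no fold is given for them. As labelled, 3647 of 16754 genes passed, 1721 higher and 1926 lower. The contrast could not be fitted without the library labelled VF untreated in ECM, so none of these values is free of it.

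In DF, matrix and contractile genes were lower in ECM than in collagen (4 libraries against 2). ELN was at -3.38 ± 0.15, DCN at -1.98 ± 0.14, COL3A1 at -1.82 ± 0.18 and ACTA2 at -2.20 ± 0.15. Of 35 matrix glycoproteins 22 were lower and 0 higher (adjusted p = 1.02e-12, and adjusted p = 0.148 with an estimated correlation). Without the 2 libraries collagen was left with 1 library, that with TGFb1, assumed to vary like the other groups. Counts from that fit compare this library with 4 in ECM, and 8 matrix glycoproteins were lower there. Of 28 contractile genes 13 were lower, LMOD1 at -1.90 ± 0.20 (adjusted p = 1.98e-08, and adjusted p = 0.339 with an estimated correlation), and of 23 collagens 11, COL8A1 at -1.36 ± 0.14 (adjusted p = 0.000133, and adjusted p = 0.341 with an estimated correlation). Without the 2 libraries 4 contractile genes and 4 collagens were lower. Inflammatory genes were lower in 16 of 21 cases, CXCL1 at -2.74 ± 0.18 and CXCL6 at -3.21 ± 0.25 (adjusted p = 2.33e-11, and adjusted p = 0.148 with an estimated correlation), and amino acid genes in 14 of 23, PSAT1 at -2.52 ± 0.15 and PHGDH at -1.63 ± 0.16 (adjusted p = 1.16e-10, and adjusted p = 0.288 with an estimated correlation). Without the 2 libraries 5 and 12 of these were lower. Proliferation genes were higher in 23 of 32 cases, AURKA at 1.49 ± 0.26 and CDK1 at 1.65 ± 0.32 (adjusted p = 1.75e-18, and adjusted p = 0.339 with an estimated correlation), and in 0 without the 2 libraries (21 at an unadjusted p under 0.05 in edgeR, DESeq2 not being run there), where AURKA stood at 1.24 ± 0.33 (adjusted p = 0.0704) and CDK1 at 1.18 ± 0.32. Cholesterol synthesis genes were higher in 11 of 20 cases, EBP at 1.23 ± 0.18 and MSMO1 at 1.01 ± 0.18 (adjusted p = 1.93e-09, and adjusted p = 0.148 with an estimated correlation), and in 5 without the 2 libraries. Mitochondrial reads were 2.00 to 2.76% in the ECM libraries and 1.06 to 1.37% in the collagen libraries, and thus moved with these gene groups. While fewer genes were called, list medians without the 2 libraries were -0.79 for matrix glycoproteins (-0.83 with all), -0.49 for contractile genes (-0.54), -0.66 for collagens (-0.71), -1.15 for amino acid genes (-1.10), -1.14 for inflammatory genes (-2.31), 0.88 for proliferation genes (1.32) and 0.66 for cholesterol genes (0.57), camera's adjusted p being at most 0.000391, and 0.139 to 0.454 with an estimated correlation. HAS2 (1.31 ± 0.23) was higher, and FN1 did not pass at -0.19 ± 0.22. MMP1 did not pass at 0.33 ± 0.44 and was at 1.41 ± 0.33 against the 1 collagen library left, where it passed. The transporter SLCO4A1 (4.30 ± 0.43), podocalyxin (PODXL, 3.23 ± 0.40) and the calcification inhibitor MGP (-8.08 ± 0.29) were at the ends. Without the library in collagen with TGFb1, CDK1 stood at 2.28 and PODXL at 3.88. HOXB13 (-6.28 ± 1.31) did not pass without the 2 libraries, nor without any 1 of 5 other libraries (adjusted p = 0.0625 to 0.113). The test called 2613 of 15791 genes, 1146 higher and 1467 lower, and 551 with 1 collagen library left, 499 of them shared. Leaving out the library in collagen with TGFb1, which also leaves 1 in collagen, gave 1439, either ECM library with TGFb1 gave 1449 and 1165, and the second untreated ECM library gave 1268. Leaving out the untreated DMEM library gave 3728. Genes called in VF for ECM against collagen under TGFb1 had a Spearman's rho of 0.617 across genes with the DF values, and 0.603 without the 2 libraries. Of 10 pericyte or smooth muscle markers 4 were lower in ECM and 2 higher (median -1.19), and of 7 epithelial markers 1 was lower and 1 higher (-0.55).

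Averaged over the 6 conditions, VF and DF differed in HOX genes. Of 30 HOX genes 25 were lower in VF and 4 higher, HOXA10 at -10.57 ± 0.18 and HOXA11 at -10.37 ± 0.17 against HOXB3 at 6.52 ± 0.12 and HOXB13 at 6.70 ± 0.13 (adjusted p = 3.03e-11, and adjusted p = 0.244 with an estimated correlation). Regional transcription factors divided, 19 of 46 higher in VF and 18 lower, with FOXP2 at 3.00 ± 0.09, TBX18 at -5.51 ± 0.11 and SHOX2 at -8.29 ± 0.18 (adjusted p = 0.77). The sodium channel SCN3A (10.15 ± 0.16), CNTNAP3B and CNTNAP3 were among the genes furthest towards VF, and the somatostatin receptor SSTR1 (-10.90 ± 0.15) among those furthest towards DF. Over the 4 conditions without the 2 libraries SCN3A stood at 11.25, CNTNAP3B at 11.69, CNTNAP3 at 11.71 and SSTR1 at -12.59, so no order among them is given. Proliferation genes were lower in VF in all 32 cases, BIRC5 at -0.95 ± 0.05 and MCM3 at -1.11 ± 0.06 (adjusted p = 2.5e-18, and adjusted p = 0.0938 with an estimated correlation). Interferon-response genes were higher in 17 of 22 cases, IFI44L at 2.82 ± 0.13 and OAS2 at 2.04 ± 0.11 (adjusted p = 3.82e-07, and adjusted p = 0.256 with an estimated correlation), and contractile genes lower in 23 of 28, ACTA2 at -1.28 ± 0.05 and CNN1 at -1.45 ± 0.06 (adjusted p = 1.02e-08, and adjusted p = 0.244 with an estimated correlation). Markers of other cell types differed with these groups. Of 10 pericyte or smooth muscle markers 6 were lower in VF and 3 higher (median -0.59), with library medians of 15 CPM in VF and 80.2 CPM in DF for NOTCH3 and of 54.2 and 2.78 CPM for ABCC9. Of 8 epithelial markers 4 were lower and 3 higher (-1.14), the keratin KRT18 having medians of 0.095 and 19.9 CPM, and of 4 endothelial markers 2 were lower and 1 higher (-0.36), with TEK at 24.1 and 1.23 CPM. These 4 markers were chosen after their values were seen. Of 6 immune markers 2 were lower and 0 higher (-1.09), and of 5 chondrocyte markers 3 were higher and 1 lower (0.41). Integrins and adhesion receptors were lower in 16 of 25 cases, ITGA8 at -7.79 ± 0.17 and N-cadherin (CDH2) at -5.56 ± 0.08 (adjusted p = 0.000132, and adjusted p = 0.256 with an estimated correlation). COL11A1 (-9.21 ± 0.16), COL18A1 (-2.66 ± 0.06), NID1 (-2.03 ± 0.05) and MMP3 (-4.52 ± 0.07) were lower in VF, and DCN (1.93 ± 0.05), COL1A1 (0.73 ± 0.06), TIMP3 (1.98 ± 0.05), the alarmin IL33 (5.03 ± 0.19) and heme oxygenase (HMOX1, 1.66 ± 0.06) were higher. Without the 2 libraries the mean was over 4 conditions, both in DMEM and those with TGFb1 in ECM and collagen, and some of these values lay farther from 0. MMP3 was then at -5.80 ± 0.08, TBX18 at -7.18 ± 0.14, CDH2 at -6.32 ± 0.09, IL33 at 6.16 ± 0.29, HOXB3 at 7.24 ± 0.16 and HOXB13 at 7.37 ± 0.17. IL33 was at 4.38 without the DF library in DMEM with TGFb1. MMP1 did not pass at -0.06 ± 0.07. With the condition of a single library left out in turn, MMP1 was 0.42 ± 0.07 without the library labelled DF untreated in collagen, 0.25 ± 0.07 without the untreated DF library in DMEM and 0.43 ± 0.07 without the untreated VF library in collagen, and passed in each of these. It also passed without the DF library in collagen with TGFb1 (-0.21) and without the library labelled VF untreated in ECM (-0.40), on the other side of 0. Several of these genes, HOXA10, HOXA11, SSTR1, SCN3A, CNTNAP3, CNTNAP3B, SHOX2, COL11A1 and ITGA8 among them, had groups with 0 reads, so their fitted values depend on the prior count and are no bounds. The test called 8658 of 17098 genes, 4253 higher and 4405 lower in VF, and 8220 over these 4 conditions, 7169 of them shared. The labels name no donors, so these differences also include any between the donors of the 2 cell types.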

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

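The tests on the 2 libraries that hold genes of both cell types and on the HOX and proliferation genes were chosen after the result was seen, while those on the matrix genes and the splits of the samples were written before theirs.

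The TGFb1 effect differed between VF and DF by the test of the difference itself in 1373 genes. TGFB3 (2.24), TNFAIP6 (1.93), BHLHE40 (1.71), CCNA2 (1.40) and AURKB (1.33) had higher effects in VF. MX2 (-2.52), ADM (-2.21), LUM (-1.70), BAMBI (-1.60), DCN (-1.44) and TXNRD1 (-0.82) had lower ones. In HOXA10, HOXC11 and ANO4, TGFb1-treated VF had 0 reads, and in BLK, MAGEC2 and CNTNAP3 treated DF had 0, so no fold is given for them. Of 100 splits of the libraries, the real one included, 1 called as many genes, and the highest of the others called 205. These splits also break up the TGFb1 effect that VF and DF share, which adds to the fitted spread. They therefore do not test the difference alone, and chance is not excluded for it.

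As labelled, the difference of the TGFb1 effect in VF between ECM and collagen passed in 3647 genes. The contrast has 1 untreated library in each medium, that in ECM being 1 of the 2 that hold genes of both cell types, so it does not separate a difference in the TGFb1 effect from the makeup of that library. The values were -8.95 for ITGA11, -7.42 for CXCL8, -6.25 for COMP, -5.83 for ACTA2, -5.18 for CXCL1, -4.84 for TNC, -4.62 for COL15A1, -4.18 for TRIB3, -4.12 for CNN1, -3.52 for CYR61, -3.43 for ELN, -2.96 for MTHFD2, -2.79 for PSAT1, -2.68 for TGFBI and -2.49 for COL3A1. FGL2 stood at 4.62 and did not pass without the second ECM library with TGFb1 (3.84).

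The libraries labelled VF untreated in ECM and DF untreated in collagen held genes of both cell types, and an exchange of their labels is argued against, since the library labelled VF held VF-only genes at 115.19 CPM and the other DF libraries at no more than 0.47 CPM. A mixture of the same 2 samples in different parts would hold every gene between 2 fixed ratios, 2.04 and 0.50 by the genes of 1 cell type alone, and 0.25% of 10595 other genes fell outside these, widened 1.25 times, against 5.98 to 29.03% between 63 other pairs of VF and DF libraries, a range that holds the bound of 20% written for them, and a second pair of thresholds had been looked at too. Replicate pairs had 0 to 0.05% outside, so any 2 like libraries pass and this share does not single out a mixture, but the same makeup of cells in both is argued against by genes not used for the ratios, the 35 at least 4-fold higher in VF having a median ratio of 2.01 (quartiles 1.72 and 2.26) and the 46 higher in DF 0.53 (0.46 and 0.60). These values go with a mixed sample, a hypothesis under which 66.38% and 32.53% of the reads would come from VF. Its DF source would exceed other DF in DF-only genes (528.97 to 945.17 CPM), as the library with 32.53% VF held 762.87 CPM. The growth condition stays open. Treated VF in ECM held at most 0.81 CPM of DF-only genes, but no other untreated library of these cells in these media was analysed. Whether such a VF source was grown without TGFb1 is open. Its VF-only genes would stand at 173.54 CPM, nearer to VF with TGFb1 (83.74 to 129.08) than to other untreated VF (1126.5 to 1260.5). TGFBI would lie under the 940 CPM of the library labelled VF, as the other held 1710. Other untreated VF held 650 to 900 and VF with TGFb1 5140 to 28800 CPM.

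Contractile, collagen and matrix genes were lower in ECM than in collagen under TGFb1 in VF, with a median of -1.59 over the 77 members called lower (quartiles -2.31 and -0.78). With the 20 genes of most reads left out, the median of the other 69 members was -1.37, and after removal of the trend on GC content and length it was -1.37. With all 8 libraries thinned to the smallest total, 10246063 reads, it was -1.49. Thinning at random keeps the ratios between groups on average, so that value decides nothing on library size. The members were chosen as lower in this same comparison, so their median lay below 0 from the outset. For these members, neither the 20 genes of most reads nor the GC and length trend accounted for the whole difference. That trend moved all genes by a median of 0.05 on the log2 scale. Without TMM scaling the median of the 77 members was -1.24. The medium itself is a biological explanation that the design names, and is open as untested beside RNA quality, since mitochondrial reads moved with it.

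HOX genes led the difference between VF and DF in their TGFb1 effect, 18 of 30 with lower values. All 18 had at most 2 reads over the 9 other VF libraries, so leaving out the library labelled VF untreated in ECM had to end these calls whatever their cause, and the 1 HOX gene that passed without the 2 libraries decides nothing on a mixed sample in the untreated arms. Proliferation genes had a median difference of 0.90 without the 2 libraries, which argues against such a mixture as the whole cause of that part, though the media of VF and DF then differ and stay open as a cause. In DMEM alone it was 1.76, a value with 1 DF library in each arm and no replicate check, which decides nothing. What else separates the cell types was not tested, and donor differences stay open.

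For the TGFb1 effect over the media in VF, 8508 genes were called, and the highest of the other splits drawn gave 6669. That split relabelled 8 of the 10 libraries and so came close to the real split turned round. In DF the count was 1934, and 0 in each of the other 33 splits with edgeR, no other tool being run on splits. For VF against DF it was 8658, and the highest of the other splits, which relabelled 2 libraries, gave 5255. Only the real split, 1 of 100, 34 and 100, reached its count. Chance among cultures or donors is open.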

How the results depend on the processing

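The fits without the 2 libraries that stood apart and of VF minus DF in DMEM alone were chosen after the results were seen. The others were planned. In DMEM alone DF had 1 library in each arm, so its values and p-values have no replicate check. Leaving out a library that was alone in its group also leaves out its medium or condition, so such values do not show which of these moved them. Among values that answer a comparison, 155 stayed within 1.5 times and 32 moved. With each library left out in turn the calls ran from 7033 to 8505 for TGFb1 in VF in DMEM, 5328 to 6968 for ECM against collagen, 7384 to 8754 for ECM against DMEM, 5863 to 7214 for collagen against DMEM, 6985 to 9093 for TGFb1 in VF over the media, 2969 to 3812 for ECM minus collagen and 7756 to 9534 for VF against DF. They ran from 1158 to 2487 for TGFb1 in DF, 950 to 2300 for VF minus DF and 551 to 3728 for ECM against collagen in DF. For ECM minus collagen 8 such fits were possible, as neither arm with a single library could be left out. With runs as separate samples these last 3 counts became 3305, 2682 and 4142, where runs of 1 sample enter as replicates. Without the 2 libraries they were 1162, 2410 and 551, the last with 1 collagen library left, and VF minus DF gave 2305 without a filter and 2476 in DMEM alone. The cause was not tested.

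With an estimated correlation camera called 0 of 21 lists in each of the 10 comparisons, with 1 to 9 lists at an unadjusted p under 0.05. Without the 2 libraries it called 1 list, TGF-beta feedback and target genes for TGFb1 in VF over the media (adjusted p = 0.0478), and for VF minus DF in DMEM alone 2, proliferation genes (adjusted p = 0.0123) and p53 targets (0.0267). With the preset correlation these fits added 10 list calls. One was that of collagens for TGFb1 in VF over the media (adjusted p = 0.000437). For TGFb1 in DF matrix glycoproteins (adjusted p = 0.0235), hypoxia genes (0.0147) and YAP/TAZ targets (0.0148) were added as higher and proliferation genes (0.0148) as lower. For VF minus DF contractile genes, collagens and collagen processing (adjusted p = 0.00444) were added. For VF against DF TGF-beta targets (adjusted p = 0.015) and amino acid genes (0.00148) were added. With an estimated correlation these 10 had adjusted p = 0.295 to 0.74. Lost were HOX genes for TGFb1 in VF (adjusted p = 0.179) and VF minus DF (0.731), and regional factors for TGFb1 in DF (0.0568). Cholesterol genes for VF minus DF (adjusted p = 0.612) and interferon genes for ECM against collagen in DF (0.555) were lost too. fry called 18 lists for TGFb1 in VF in DMEM (8 with the preset correlation), 5 for TGFb1 in DF (8), 3 for VF minus DF (7) and 19 for VF against DF (7). The share of opposite signs between TGFb1 in DMEM and ECM against collagen was 51.5% over all genes, 53% with DESeq2 and 52.6% with RLE.

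Of 4568 values of named genes under alternatives, 4483 stayed on their side of the threshold, 55 were no longer past the threshold, 16 were newly past it and 14 changed sign while past it in at least 1 of the 2 fits. A further 17, counted among the 4483, changed sign while past it in neither, such as COL1A1 for VF minus DF in DMEM alone (-0.27). For VF minus DF, ACTA2, which had no direction with all libraries (adjusted p = 0.991), stood at 1.57 without the 2 libraries, 1.67 without the library labelled VF untreated in ECM and 1.59 in DMEM alone. HOXA10 became 0.16 and 0.07 and ANO4 0.65 and 0.50 there, but the VF libraries left had 0 reads in both arms, so these fitted values (adjusted p = 1) measure neither a change nor a turned direction. The same holds in DMEM alone for HOXA10 (0.29) and ANO4 (0.84), and for BLK (-2.08) and CNTNAP3 (-0.02), of which DF had 0 reads in both arms. Over single libraries left out, HOXA10 ran from -9.84 to 0.07, ANO4 from -9.80 to 0.50 and ACTA2 from -1.02 to 1.67. MMP1 in VF against DF became 0.42, 0.25 and 0.43 without the untreated libraries of DF in collagen, DF in DMEM and VF in collagen. It stayed within -0.40 to 0.43 over all libraries left out. With DESeq2 the medians of matrix glycoproteins and proteases for TGFb1 in VF over the media went from 0.30 to -0.02 and from 0.01 to -0.03, and that of hyaluronan genes for ECM against collagen in DF from -0.03 to 0.21.

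With the replicate number as a block, the counts were 8641, 7060, 8905 and 7546 for the 4 comparisons of 8 VF libraries, and 154 of 154 named values stayed on their side. Deviations of libraries with the same number correlated at 0.004 to 0.061 over 6 pairs of groups, so the numbers do not pair the samples. Depth limits the low genes: a floor of 3 counts was 0.293 CPM in the shallowest library.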

Other observations

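Of the gene groups not described above for TGFb1 in VF in DMEM, 1 passed as a list. Hypoxia and glycolysis genes rose in 18 of 22 cases and fell in 1, and 19 passed when adjusted over the list alone, the glycolytic enzyme ENO1 at 1.55 ± 0.07 and ADM at -3.42 ± 0.09 (camera adjusted p = 3.14e-08, and adjusted p = 0.14 with an estimated correlation). The other lists did not pass. Oxidative stress genes were lower in 8 of 17 cases and higher in 6, NQO1 at -1.40 ± 0.08 (adjusted p = 0.129). YAP/TAZ targets were higher in 11 of 22 cases and lower in 5, with CTGF at 1.87 ± 0.08 (adjusted p = 0.0886). Integrins and adhesion receptors were higher in 11 of 23 cases and lower in 7, ITGB3 at 4.42 ± 0.16 and ITGB8 at -4.42 ± 0.15 (adjusted p = 0.0546). For p53 targets 4 of 19 were higher and 11 lower (adjusted p = 0.147), and for regional transcription factors 11 of 36 were higher and 20 lower, FOXD1 at 3.29 ± 0.10 (adjusted p = 0.0798). Of 10 hyaluronan genes 4 were higher and 3 lower, TNFAIP6 at 3.58 ± 0.12 (adjusted p = 0.695). Of 21 cholesterol genes 5 were higher and 6 lower, with a median of 0.05, a mean of -0.03 and a direction of up in camera (adjusted p = 0.822). Of 4 ID genes 3 were higher and 1 lower, ID2 at -1.35 ± 0.07 (adjusted p = 0.587), and of 4 HOX genes 3 were lower, HOXB13 at -1.43 ± 0.09 (adjusted p = 0.104). Proteases as a list did not pass either (adjusted p = 0.293).

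In ECM against collagen under TGFb1, cholesterol genes were higher in 11 of 21 cases and lower in 2, with 16 past when adjusted over the list alone, INSIG1 at 0.68 ± 0.07 (adjusted p = 0.00659, and adjusted p = 0.0899 with an estimated correlation). Targets of p53 were lower in 12 of 19 cases and higher in 4, the stress cytokine GDF15 at -2.42 ± 0.15 and CDKN1A at -0.83 ± 0.07 (adjusted p = 0.00435, and adjusted p = 0.0899 with an estimated correlation). Integrins and adhesion receptors were lower in 13 of 23 cases and higher in 6, the collagen-binding ITGA1 at -1.94 ± 0.09 (adjusted p = 0.0417, and adjusted p = 0.238 with an estimated correlation). All 4 HOX genes tested were higher, HOXB3 at 0.75 ± 0.09 (adjusted p = 0.00712, and adjusted p = 0.114 with an estimated correlation). Metallothionein MT2A was at 2.15 ± 0.09, though the oxidative stress list did not pass, 5 of 17 higher and 5 lower (adjusted p = 0.453). Hypoxia genes were higher in 10 of 22 cases and lower in 6 (adjusted p = 0.368), ligands, receptors and SMADs higher in 5 of 22 and lower in 7 (adjusted p = 0.182), and regional transcription factors higher in 11 of 36 and lower in 11 (adjusted p = 0.902). Of 4 ID genes 1 was higher and 2 lower, with a median of -0.07, a mean of 0.03 and a direction of down (adjusted p = 0.902). With the members that had groups at or near 0 reads set to their bounds, the median of contractile genes went from -1.19 to -1.12 and that of interferon-response genes from -1.33 to -1.24.

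Between the cell types, the TGFb1 effects over the media, which share no library, had a Spearman's rho of 0.804 across the genes called in VF, and 0.734 without the 2 libraries, where the effect in VF is over DMEM and collagen and that in DF over DMEM and ECM. In both, 689 genes were higher, where independent lists would share 221.7, and 929 were lower, where they would share 276.3. These counts were 461 (153.4 for independent lists) and 521 (163) without the 2 libraries. With all libraries the untreated arms include those 2, which hold genes of both cell types, so part of that overlap is not separated from their makeup. Medians over 1 CPM were reached in VF and DF by 4 and 6 of 14 epithelial markers, DSP up to 1320 CPM, by 1 and 1 of 10 endothelial markers, TEK up to 48.4 CPM, and by 1 and 2 of 12 skeletal muscle markers. For pericytes or smooth muscle they were 8 and 8 of 10, a set that holds ACTA2, for chondrocytes 5 and 5 of 9, SOX9 up to 81.5 CPM, for melanocytes 2 and 1 of 7, MITF up to 72.1 CPM, for adipocytes 1 and 0 of 8, and for Schwann cells or nerve 1 and 2 of 8.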
